A study of Homo sapiens with 2 samples.

How the data were processed

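Total RNA of HaCaT keratinocytes was labelled with Cy3 by the submitters and hybridised to 2 arrays, 1 for cells given a negative control siRNA and 1 for cells labelled as NUP153 knocked down. Groups were taken from the sample labels. The design text of the series states that the conditions had no biological replicates. Both arrays lay on 1 slide and were scanned together, per the file headers, so slide and scan did not differ between the groups.

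The deposited values are spot intensities from Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. The processed signal of each spot is an intensity on a linear scale from which the background had been subtracted by the software, per the file headers. A table of the authors' processed values was also deposited, as a linear intensity ratio to a factor of its own for each array. It held 23840 probes, and its columns had medians of 0.399 for the control array and 0.402 for the array labelled NUP153 siRNA. Set against the scanner intensities, a value of 1 equalled an intensity of 1159 on the control array and 1477 on the other, and 99.1% and 99.6% of probes lay within 1% of that factor. The scale was therefore linear, genes were not centred, and each column followed its own array in direction. The rule behind the factor stays unknown, as do the steps between the scanner values and that table.

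Control spots and spots marked as outliers on either array were left out, which removed 860 of 43118 spots and all spots of 59 probes. Saturated spots were to be kept, and there were 0. Each array's 75th percentile of the log2 processed signal was subtracted, and the log2 ratio was the array labelled NUP153 siRNA minus control. The 75th percentile lay at an intensity of 1468 on the control array and 1835 on the other, a shift of 0.32 on the log2 scale, and the median shift of 5 bright spike-in probes was 0.36. Spots of a probe were averaged; 999 probes were spotted 10 times. A probe counted as well above background where more than 50% of its spots were marked so. Of the probes kept, 21533 were well above background on both arrays and are called measured, 547 only on the control array, 1703 only on the array labelled NUP153 siRNA and 10285 on neither. A gene was measured with at least 1 measured probe, and its ratio was the mean over its measured probes. Of the 13976 measured genes, 3307 had more than 1 such probe, with a median SD between probes of 0.19. The files hold no gene symbols, so probes were named by unversioned RefSeq accession through a gene table of GRCh38.p14. This named 25721 probes and left 8347 without a symbol. The files name another genome build, so no coordinates are given.

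A gene detected on 1 array only was given as a bound. The bright array's normalized signal was set against the higher of the dim probe's own signal and the lowest signal among probes well above background on the dim array, which was -5.98 for the control array and -6.32 for the other. Genes were counted at 2-fold. No test was run, since each group held 1 array. For each list with at least 5 measured members, the median ratio was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins.

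Before the data were examined, the groups, the values and filters above, most alternatives, 31 gene lists and the rule for named genes were fixed. The lists were other nucleoporins, nuclear transport receptors, basal keratinocyte genes, squamous lineage regulators, AP-1 and immediate early genes, epidermal differentiation genes, keratinocyte activation genes, simple epithelial genes, mesenchymal genes, TGF-beta response genes, YAP and TEAD targets, Notch targets, G1/S genes, G2/M genes, p53 targets, interferon response genes, NF-kB and cytokine genes, EGFR ligands and feedback genes, unfolded protein response genes, ATF4 targets, hypoxia genes, cholesterol synthesis genes, NRF2 targets, histone genes, ribosomal protein genes, reference genes, chromatin and super-enhancer regulators, and markers of melanocytes, endothelium, leukocytes and neurons. The rule named NUP153, TP63 and SOX2, and the 10 genes with the highest and the 10 with the lowest ratio. These had to carry a proper symbol, a signal on the brighter array at or above the median of measured genes, and 1 sign at every measured probe. It also named up to 4 members per list with the largest absolute ratio, any member of the basal, squamous regulator and differentiation lists, and the 3 largest bounds in each direction. Some genes that the rule would name are not reported here. Other genes with only a bound that are named among the lists, and genes of the closing observations, were chosen after their values were seen. A further 3 lists, of syncytiotrophoblast, airway secretory and intestinal genes, were added later to test for RNA from other cells.

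Alternatives were normexp background correction with an offset of 50, quantile, median and loess normalization (span 0.3), no filter on dim probes, a filter at the median signal, the brightest probe in place of the mean, the authors' processed values, thresholds of 1.5-fold and 3-fold, and random lists without matching. Mean spot signals were not among the columns, so normexp ran on median spot signals and median local backgrounds. Scaling by spike-in probes, and normexp fitted without 5 spots of aberrant background, were added after the data were seen. The refitted normexp kept the offset of 50, which pulls the ratios of dim genes toward 0 by construction. The steps were tested on simulated data with 13976 genes: 1.49% of 67 genes altered by 1.5-fold, 56.7% of 67 altered by 2-fold and 100% of 66 altered by 4-fold were called at 2-fold with the right sign, and 0% of unaltered genes were called. A list shifted by 0.5 lay at percentile 100, and 5 of 5 unshifted lists lay in the central 95%. The simulated noise was normal with an SD of 0.19 for every gene, the median SD between probes. The pooled SD between probes was larger, at 0.39, and differences between cultures and extra noise of dim probes were not simulated. The 0% of unaltered genes called therefore does not estimate false calls in the real data. Noise was drawn separately for each gene, so members of a list that vary together were not simulated. The result for the 5 unshifted lists therefore does not show how often real lists leave the central 95%. Values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, alternatives with limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9.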

Results

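RNA levels were measured in HaCaT cells, a spontaneously immortalized line of human skin keratinocytes, on 2 single-colour Agilent arrays. The first array held total RNA from cells transfected with a negative control siRNA, and the other held RNA from cells that the labels describe as knocked down for NUP153. NUP153 is a nucleoporin of the nuclear basket, the filamentous structure on the inner face of the nuclear pore. RNA was taken 3 days after transfection, and 0.2 µg was labelled per array. Each group held 1 array, so no difference has a replicate check, no test across arrays was possible and no p-value is given. The number of arrays limits the precision, and each value describes these 2 RNA samples. Of 34068 probes, 22080 (64.8%) were well above background on the control array and 23236 (68.2%) on the array labelled NUP153 siRNA. The median intensity was 160 on the control array and 211 on the other, and no spot was saturated. Over the 21533 probes measured on both arrays, the normalized log2 signals correlated with a Pearson r of 0.975 across probes, which are not independent replicates. Technical error within an array was small against the differences described: the SD of the log2 ratio over replicate spots of a probe had a median of 0.052 over 713 probes. Different probes of the same gene varied more, with a pooled SD of the log2 ratio of 0.39.

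The series concerns the part that the nuclear pore plays in holding super-enhancers in squamous cells, and the comparison asks which transcripts differ when NUP153 is targeted. NUP153 itself, the gene that checks the labels, differed little between the arrays. Its normalized log2 signal was 0.46 on the control array and 0.29 on the array labelled NUP153 siRNA, a log2 ratio of -0.17, or 11.4% lower. The value rests on 1 probe, A_33_P3306510, and 4639 of the 13976 measured genes had a lower ratio than NUP153. The RNA values therefore do not show a knockdown of NUP153 on day 3, so the group is called the array labelled NUP153 siRNA throughout, and every direction below rests on that label. Protein was not measured in the data used here, and the sequence of the siRNA is not given in the sources used here, so whether the probe reads every transcript that the siRNA targets is unknown.

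Although NUP153 differed little, many keratinocyte genes differed by a wide margin. On the array labelled NUP153 siRNA, the early differentiation keratin KRT1 and the cornified envelope precursor IVL were far higher, together with several genes that are better known from other epithelia. These included SCGB1A1, a secretoglobin of airway secretory cells, AOC1, a diamine oxidase, and PSG2, PSG3 and PSG5, pregnancy-specific glycoproteins of the placenta. Far lower were the squamous cell carcinoma antigens SERPINB3 and SERPINB4, the matrix metalloproteinases MMP1 and MMP10, and the transcription factor SOX2. TP63, which encodes the master regulator of stratified epithelium, was lower as well. Of the measured genes, 612 (4.38%) were at least 2-fold higher on the array labelled NUP153 siRNA, 523 (3.74%) were at least 2-fold lower, and 12841 lay within 2-fold. At 4-fold or more, 132 genes were higher and 111 lower, and at 8-fold or more, 43 were higher and 30 lower. A background correction by normexp gave 300 higher and 3880 lower genes, so that 7.18% of the calls were higher in place of 53.9%. That correction was distorted by 5 spots of the control array, and a refitted normexp correction without them gave 379 and 333.

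The genes that stood highest among well expressed ones were led by VAPA, a membrane protein of the endoplasmic reticulum, with a log2 ratio of 5.71 (52.2-fold). VAPA is expressed broadly, yet its only measured probe gave a control signal of -4.82, near background, so this ratio is uncertain. AOC1 followed with 5.70 (52.2-fold), PSG3 with 5.35 (40.9-fold) and PHGR1, a small protein of the intestinal epithelium, with 5.15 (35.4-fold). PSG2 had a log2 ratio of 4.75 (27.0-fold) and PSG5 of 4.70 (26.1-fold). The PSG genes are near-identical copies of each other, so a probe can read several of them and the values of single members are uncertain. SCGB1A1 lay above the 75th percentile of both arrays and stood at 4.74 (26.7-fold). KRT1 reached 4.63 (24.7-fold), the raft protein gene MAL 4.54 (23.2-fold) and SUSD2 4.52 (22.9-fold). The control signals of AOC1 (-5.15), PSG3 (-4.37), PHGR1 (-4.54), MAL (-4.48) and SUSD2 (-4.82) were near background too, so the sizes of these ratios are uncertain. With the refitted normexp correction the ratios were 4.54 for VAPA, 4.21 for AOC1, 4.35 for PSG3, 4.0 for PHGR1, 3.92 for PSG2, 3.51 for MAL and 3.33 for SUSD2. VAPA was at 3.63 without the filter on dim probes. Among genes well above background only on the array labelled NUP153 siRNA, the neuregulin gene NRG2 was at least 60.6-fold higher, the Wnt ligand gene WNT11 at least 57.2-fold and the imprinted non-coding RNA H19 at least 40.9-fold. In all, 855 genes were detected on that array only, 219 of them with a bound of at least 2-fold. That array was also brighter before scaling, with a 75th percentile of 1835 against 1468. Its lowest signal well above background was lower too, at -6.32 against -5.98. The number detected there only therefore does not by itself show that more genes were expressed.

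**Figure D1:**
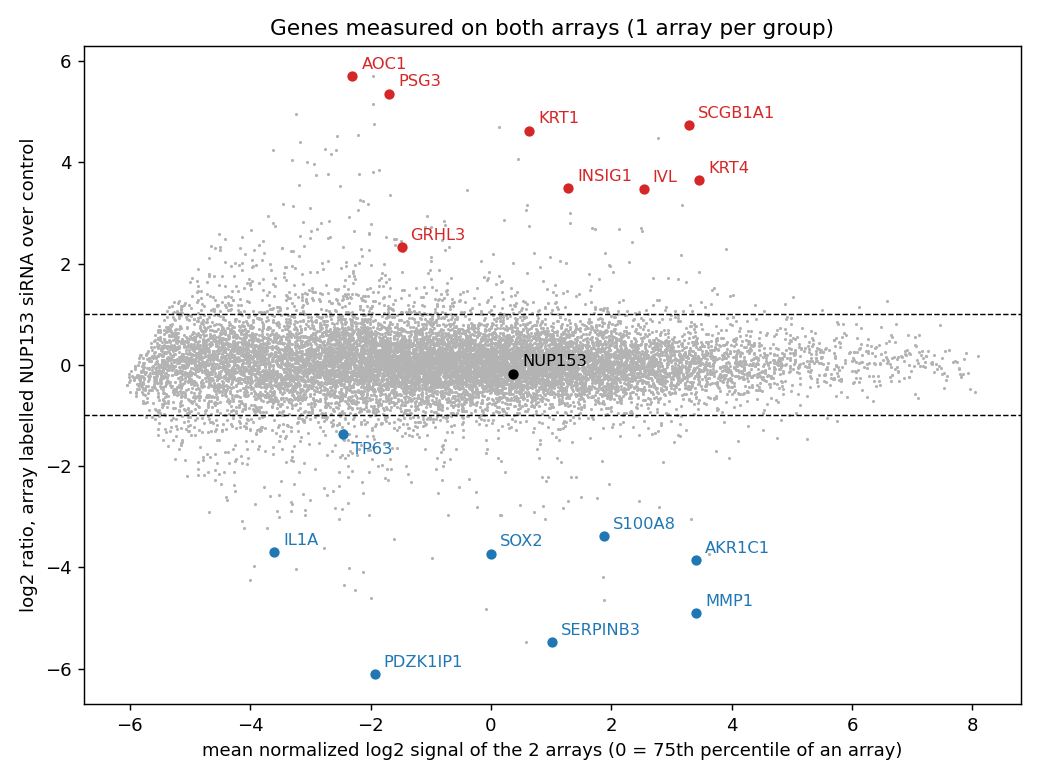
Each point is 1 of the 13976 measured genes. The x axis gives the mean normalized log2 signal of both arrays, the y axis gives the log2 ratio of the array labelled NUP153 siRNA over control, and the dashed lines mark 2-fold. NUP153 (black) lies near 0 at -0.17, while KRT1 (4.63) and SERPINB3 (-5.48) are among the labelled genes far above (red) and below (blue) the lines.

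The gene with the lowest ratio was PDZK1IP1, a small membrane protein also known as MAP17, at -6.11 (69.1-fold lower). SERPINB3 and SERPINB4, near-identical protease inhibitor genes whose probes can read each other, were both at -5.48 (44.6-fold and 44.5-fold lower). The interstitial collagenase MMP1 had a log2 ratio of -4.90 (29.9-fold lower) and the stromelysin MMP10 of -4.82 (28.2-fold lower). BASP1 was at -4.64, the protease inhibitor SERPINE2 at -4.61, the ganglioside synthase B4GALNT1 at -4.45, the placental growth factor PGF at -4.35 and the complement protease C1S at -4.18. The refitted normexp correction gave -4.91 for PDZK1IP1, -3.81 for SERPINE2, -3.64 for B4GALNT1 and -3.52 for PGF. On the array labelled NUP153 siRNA, the signals of these genes were near background (-4.98, -4.30, -4.48 and -4.62). The sizes of their ratios are therefore uncertain. SOX2 had a ratio of -3.73, 13.2-fold lower, and TP63 of -1.37, 2.59-fold lower, each from 1 probe. The TP63 probe is annotated to 1 transcript, and whether it reads every TP63 transcript is unknown. Among genes detected on the control array only, TMEM71 was at least 39.5-fold lower, the secreted phospholipase PLA2G2F at least 27.3-fold and the gastrin receptor CCKBR at least 20.4-fold. There were 293 such genes, 178 with a bound of at least 2-fold.

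Genes of epidermal differentiation stood higher as a group on the array labelled NUP153 siRNA, while the keratins of the basal layer differed little. The higher members spanned the program, from the early suprabasal keratins KRT1 and KRT10 to the envelope proteins IVL and SCEL and the hair follicle and granular layer protein TCHH. KRT5 and KRT14, the keratin pair of basal cells, were slightly higher on the same array. Of 62 differentiation genes, 46 were measured: 19 were at least 2-fold higher, 1 was at least 2-fold lower (CERS3, a ceramide synthase, -1.29), and 36 in all had a ratio above 0 against 10 below. The list median was 0.65, above the medians of all 10000 random lists of equal size and signal (percentile 100). KRT4 stood at 3.65, IVL at 3.48, SCEL at 3.45, SERPINB2 at 2.92, TCHH at 2.83, CALML5 at 2.06, KRT10 at 1.36 and the crosslinking enzyme TGM1 at 0.91. The late barrier proteins FLG (1.04) and LORICRIN (1.09) were measured, but with low signals on both arrays. The other members with an absolute ratio near 1 included CSTA at -0.97, and FLG2 and TCHHL1 were detected on the array labelled NUP153 siRNA only. Probes disagreed for SPRR1A, with ratios of 0.10 and 3.19, and for LCE1C, with -0.40 and 3.18, both members of families of near-identical genes. With the distorted normexp correction, the list median turned to -0.17 and the ratios of FLG, LORICRIN and LCE1C turned negative. With the refitted normexp correction the median was 0.42 and 15 genes were at least 2-fold higher, without FLG (0.25), LORICRIN (0.43) and LCE1C (0.66), and SERPINB2 was at 2.24. FLG was at 3.33 without the filter on dim probes, and SPRR1A at 0.10 with the brightest probe.

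Basal keratinocyte genes, which include hemidesmosome components and basal keratins, did not stand apart as a list. Of 30 measured members, 1 was at least 2-fold higher, 2 were at least 2-fold lower and 27 lay between, and the median of -0.0015 was at percentile 40.3. KRT5 and KRT14 both had a ratio of 0.43, KRT15 of 0.23, the hemidesmosome integrins ITGA6 of 0.36 and ITGB4 of 0.08, and the laminin chain LAMA3 of -0.81. The chemokine CXCL14 stood at 2.30, which turned to -0.40 with the distorted normexp correction and was 1.36 with the refitted one, and the parathyroid hormone-like PTHLH at -1.23. Regulators of the squamous lineage were mixed: 3 of 35 measured were at least 2-fold higher, 3 at least 2-fold lower and 29 between, and 27 had a ratio above 0. GRHL3, a factor of terminal differentiation, was at 2.33 (1.09 without the filter on dim probes), the helix-loop-helix inhibitor ID2 at 1.95 and MAF, a factor of late differentiation, at 1.19. The lower members were SOX2, TP63 and PRDM1 (-1.50, but -0.92 with the refitted normexp correction), while KLF4 (0.19), KLF5 (0.14) and ZNF750 (0.07) differed little, and CEBPB stood at -0.97. The list median of 0.23 was at percentile 98.9, and it was -0.017 with the distorted normexp correction.

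**Figure D2:**
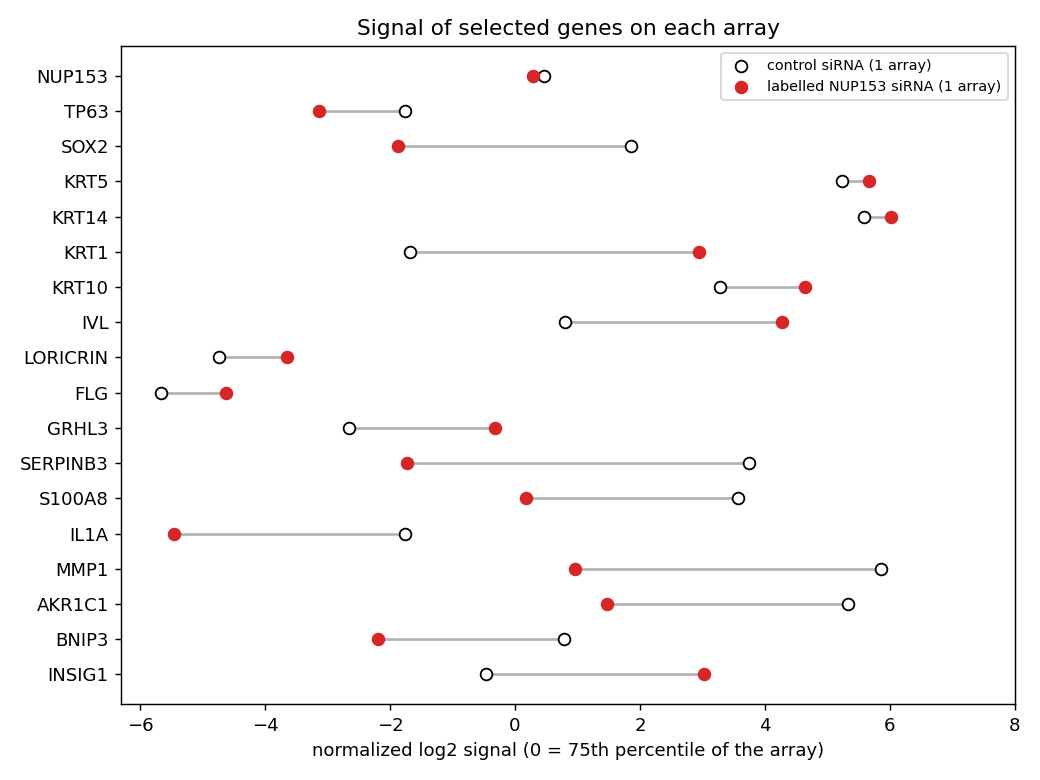
Normalized log2 signal (x axis, 0 at the 75th percentile of the array) of selected genes on the control array (open circles) and on the array labelled NUP153 siRNA (filled circles), with 1 array per group and no error bars. The circles nearly coincide for NUP153 (0.46 and 0.29) and lie far apart for IVL (0.80 and 4.28) and SERPINB3 (3.75 and -1.73).

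Genes of keratinocyte activation and inflammation stood lower on the array labelled NUP153 siRNA. SERPINB3 and SERPINB4, described above, were the lowest of the activation genes, and the alarmins S100A8 and S100A9, which pair as calprotectin, and the cytokine genes IL1A, TNF and CXCL8 were lower too. Leukocyte marker genes stood lower with them, 9 of 10 measured having a ratio below 0 and a median of -0.47 (percentile 0.30). Of 18 measured keratinocyte activation genes, 9 were at least 2-fold lower and none was at least 2-fold higher, and the median of -0.80 lay below all random lists (percentile 0). S100A8 had a ratio of -3.38 and S100A9 of -2.61, and 3 further members, IL36G, S100A7A and KRT6B, were detected on the control array only. Of 25 measured NF-kB and cytokine genes, 10 were at least 2-fold lower and 0 higher, with a median of -0.86 (percentile 0), and the chemokine CCL20, detected on the control array only, was at least 7.54-fold lower. IL1A stood at -3.70, TNF at -2.55, the neutrophil chemokines CXCL8 at -2.34 and CXCL2 at -2.07. With the refitted normexp correction they were at -2.48, -1.83, -1.70 and -1.43, and CXCL2 was at -1.47 with the brightest probe or the filter at the median signal. The signals of IL1A (-5.45), TNF (-4.39) and CXCL8 (-4.45) on the array labelled NUP153 siRNA were near background, so the sizes of their ratios are uncertain. Among 30 AP-1 and immediate early genes, 5 were at least 2-fold lower and 0 higher, with a median of -0.14 (percentile 5.20). They included the AP-1 subunit FOSL1 (-2.15), the factors ETV4 (-1.58) and EGR2 (-1.32), and the immediate early gene IER3 (-1.12). EGR2 was within 2-fold with the refitted normexp correction. That correction left 3 lower and 0 higher, and the filter at the median signal, with 20 of the genes measured, gave 2 lower and 1 higher. EGFR ligands and feedback genes were mixed, with 2 of 12 measured at least 2-fold lower, 0 higher and a median of -0.051 (percentile 34.1), while NRG2, detected on the array labelled NUP153 siRNA only, was at least 60.6-fold higher. The feedback inhibitor LRIG1 was at -2.29 (-1.62 with the refitted normexp correction), the ligand HBEGF at -1.64, the receptor ERBB2 at 0.95 and the ligand EPGN at 0.92, which turned to -1.19 with the distorted normexp correction.

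Genes of sterol synthesis stood higher on the array labelled NUP153 siRNA, whereas genes of the oxidative stress and hypoxia responses stood lower. INSIG1, the sterol-sensing regulator of the pathway, and MVK, the mevalonate kinase, were both higher. AKR1C1 and AKR1C3, aldo-keto reductases under the factor NRF2, were far lower, as was BNIP3, a hypoxia-induced mitophagy receptor. Of 25 measured cholesterol synthesis genes, 10 were at least 2-fold higher, 0 were at least 2-fold lower and 24 had a ratio above 0. Their median of 0.93 lay at percentile 100, with INSIG1 at 3.49 (11.3-fold) and MVK at 1.72 (3.29-fold). Of 22 NRF2 target genes, 9 were at least 2-fold lower and 0 higher, with a median of -0.85 (percentile 0). AKR1C1 (-3.85) and AKR1C3 (-3.74) are near-identical copies and uncertain as single genes, AKR1B10 was at -2.79 and the cystine transporter SLC7A11 at -2.13. Of 23 hypoxia genes, 5 were at least 2-fold lower and 0 higher, with a median of -0.56 (percentile 0), led by BNIP3 (-2.97), ANGPTL4 (-2.50), NDRG1 (-1.71) and the pyruvate dehydrogenase kinase PDK1 (-1.40). Detected on the control array only, the hypoxia marker CA9 was at least 12.4-fold lower and LOX at least 2.05-fold. ATF4 target genes had a median of -0.27 (percentile 0.17), with 1 of 28 at least 2-fold higher (CTH, 1.04) and 3 lower (SLC7A11, CHAC1 at -1.51 and STC2 at -1.03), of which CTH and STC2 were within 2-fold with the refitted normexp correction. Unfolded protein response genes had a median of -0.24 (percentile 0.805) although the 2 of 23 that passed 2-fold, DNAJC3 (1.53) and HERPUD1 (1.39), were higher; CREB3L2 was at -0.89.

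Genes of DNA replication stood slightly lower on the array labelled NUP153 siRNA and genes of mitosis differed little. BLM, a helicase, and POLE2 and ORC1, parts of the replication machinery, were the G1/S genes past 2-fold. Of 55 measured G1/S genes, 3 were at least 2-fold lower, 0 higher and 42 had a ratio below 0, with a median of -0.39 (percentile 0). BLM was at -1.15, POLE2 at -1.09, ORC1 at -1.02, which was within 2-fold with the refitted normexp correction, and the licensing factor CDT1 at -0.99. Of 64 G2/M genes, 1 was at least 2-fold higher and 0 lower, with a median of -0.088 (percentile 7.22). That gene was SPC24, at 1.45 and close to background, which turned to -1.39 with the distorted normexp correction and was 0.63 with the refitted correction, so that no G2/M gene passed 2-fold, and the checkpoint kinase BUB1B was at -0.70. Replication-dependent histone genes stood higher, with 4 of 25 at least 2-fold higher, 0 lower and a median of 0.57 (percentile 100). They were H2AC8 (1.25), H2BC3 (1.24), H2BC5 and H2BC12 (1.08). Genes of 1 histone type have near-identical copies, so these values are uncertain as single genes. Of 34 p53 target genes, 5 were at least 2-fold higher and 2 lower, with a median of 0.25 (percentile 99.1) that was -0.29 with the distorted normexp correction. TIGAR, a regulator of glycolysis, stood at 1.55, TP53INP1 at 1.43, the antiproliferative BTG2 at 1.25 and the mitochondrial quality gene SPATA18 at -1.80 (-1.18 with the refitted normexp correction).

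Targets of YAP and TEAD, the effectors of Hippo signalling, stood higher on the array labelled NUP153 siRNA. Of 19 measured, 4 were at least 2-fold higher and 0 lower, and 2 more, ANKRD1 and CCN2, were detected on that array only. The median was 0.61 (percentile 100), with GADD45B at 1.41 and AMOTL2 at 1.14. TGFB2 at 1.97 and WTIP at 1.65 were close to background on the control array and turned to -1.13 and -0.97 with the distorted normexp correction. They were 0.83 and 0.91, within 2-fold, with the refitted correction, under which 3 of 19 were at least 2-fold higher. TGF-beta response genes went both ways, with 2 of 21 at least 2-fold higher, 3 lower and a median of -0.26 (percentile 1.37). The cell cycle inhibitor CDKN2B was at 2.24 (-0.21 with the distorted normexp correction and 1.47 with the refitted one), the pseudoreceptor BAMBI at 1.13, ANGPTL4 at -2.50 and the collagen chain COL4A1 at -1.13, which was just within 2-fold with the refitted correction. CCN2, detected on the array labelled NUP153 siRNA only, was at least 2-fold higher. Of 11 Notch target genes, none passed 2-fold in either direction; the median was 0.30 (percentile 96.7) and HES5 lay just under 2-fold at 1.00. Interferon response genes were split, with 3 of 39 at least 2-fold higher, 6 lower and a median of -0.068 (percentile 20.4), and CXCL11, detected on the array labelled NUP153 siRNA only, was at least 4.54-fold higher. With the refitted normexp correction 2 were higher and 4 lower. IFI44L was at -2.61 (-1.48 with that correction), the antiviral GTPase MX1 at -1.92, IFI6 at -1.73 and IFIT2 at 1.49.

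Most other components of the nuclear pore differed little, with the exception of NUP210L, a paralog of the pore membrane protein NUP210. Of 30 other nucleoporins measured, none was 2-fold higher or lower, and the median was -0.11 (percentile 11.1). NUP210L was detected on the control array only and was at least 5.64-fold lower. The members farthest from 0 were AAAS (-0.69), NUP155 (-0.68), NUP210 (-0.67) and NUP93 (-0.57). Of 32 nuclear transport receptors, 2 were at least 2-fold lower and 0 higher, with a median of -0.12 (percentile 7.88). They were the importins KPNA7 (-1.22, within 2-fold with the refitted normexp correction) and IPO13 (-1.18), followed by the tRNA exportin XPOT (-0.94) and IPO4 (-0.78). Chromatin and super-enhancer regulators had a median of 0.20 (percentile 98.1), with 1 of 32 at least 2-fold higher and 0 lower. That gene was the histone demethylase KDM6A at 1.35, from probes at 0.81 and 1.89. It was 0.83 with the refitted normexp correction, 0.81 with the brightest probe or the filter at the median signal and -0.31 with the distorted correction, so the call at 2-fold did not hold. The Mediator subunit MED14 was at 0.89.

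Lists that describe general expression shifted little. Of 54 ribosomal protein genes, none passed 2-fold and the median was 0.17 (percentile 99.3), with RPS16 highest at 0.76. Of 28 reference genes, 1 was at least 2-fold higher and 1 lower, with a median of -0.018 (percentile 32.2). They were REEP5 (1.17) and the glycolytic enzyme GPI (-1.45), and PGK1, another glycolytic enzyme, lay just short of 2-fold lower. Markers of other cell types differed from list to list. Simple epithelial genes had 2 of 14 at least 2-fold higher, 0 lower and a median of -0.12 (percentile 14.9). KRT23 at 2.28 and the mucin MUC16 at 2.19 were close to background on the control array and turned to -0.99 and -0.86 with the distorted normexp correction. They were at 1.14 and 1.05 with the refitted one, MUC16 was at 1.31 without the filter on dim probes, and MUC1 was at -0.95. Mesenchymal genes had 2 of 12 at least 2-fold higher and 3 lower, with a median of 0.14 (percentile 79.6). The proteoglycan DCN stood at 2.93 and TAGLN at 2.79, against -1.66 for the cadherin CDH2 and -1.53 for the actin ACTA2. With the refitted normexp correction, 2 were higher and 2 lower. Detected on 1 array only, the proteoglycan LUM was at least 10.0-fold higher and ZEB1 at least 2.18-fold higher, and VIM was at least 3.38-fold lower. Of 5 melanocyte genes, 1 was at least 2-fold higher (MITF, 1.17) and 0 lower, with a median of 0.36 (percentile 89.8). Leukocyte genes had a median of -0.47 (percentile 0.30), with 2 of 10 at least 2-fold lower, CD68 (-1.23) and CD14 (-1.13), and 0 higher, and CD3E, detected on the control array only, was at least 4.99-fold lower. Neuronal genes had a median of -0.38 (percentile 4.79), with 0 of 6 past 2-fold and SYT1 at -0.85. Of 11 endothelial genes, 2 were measured, too few for a median, and 1 of them, VWF, stood at 1.29, which was within 2-fold with the refitted correction and turned to -0.35 with the distorted one. Of the 30 lists with a median, 8 lay above the central 95% of their random lists and 9 below it, as a description of these 2 arrays and not a test of the conditions.

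**Figure D3:**
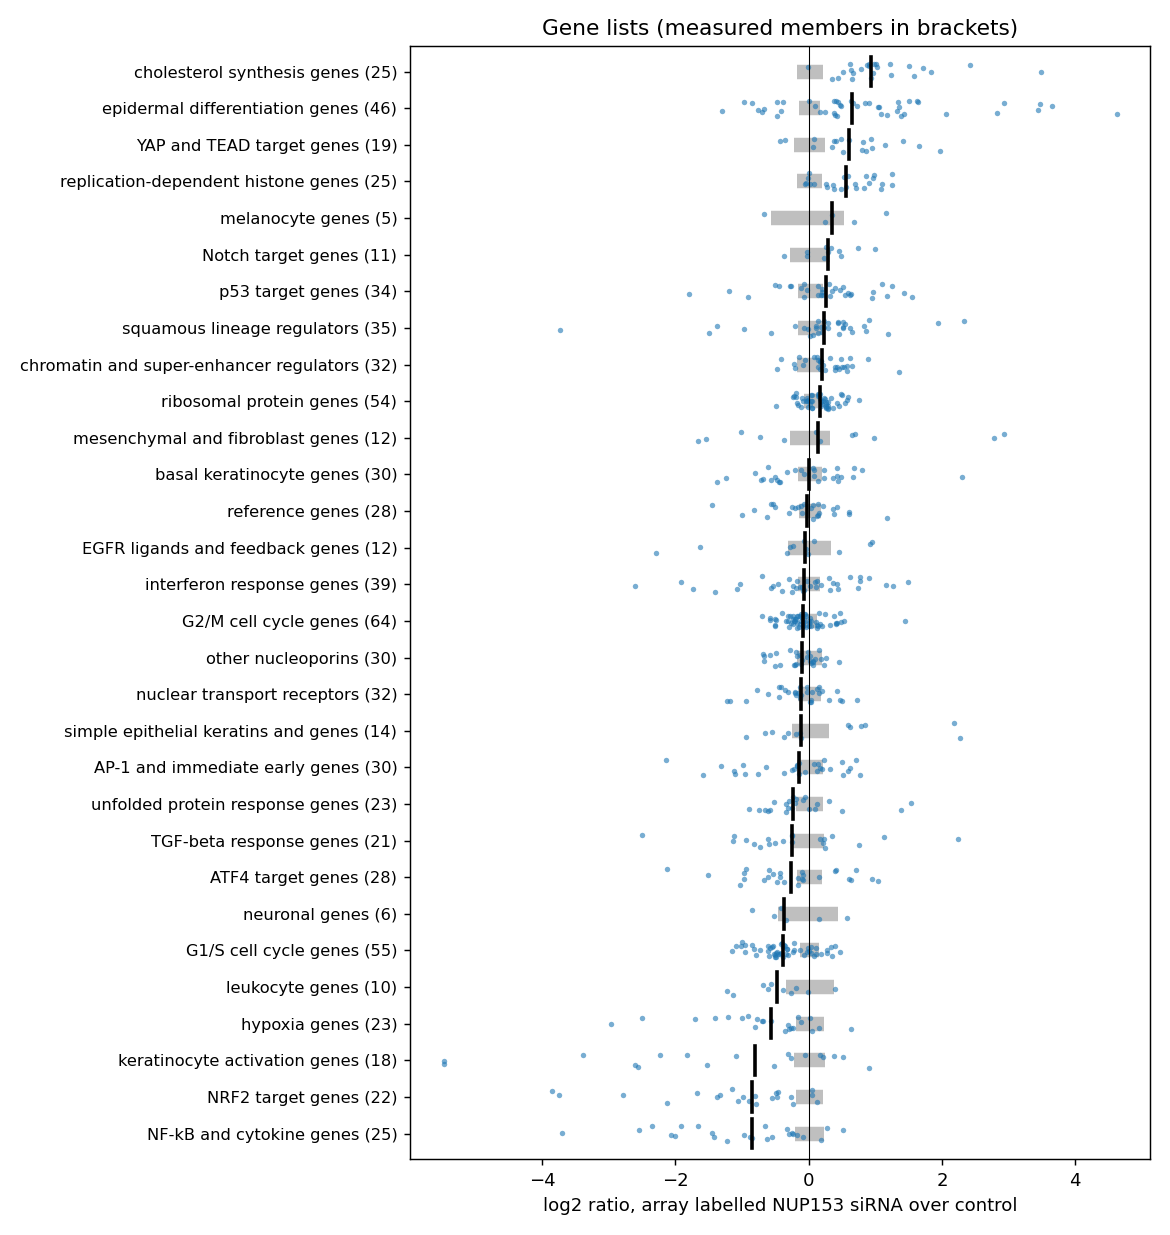
Log2 ratio of the array labelled NUP153 siRNA over control (x axis) for the measured members (points) of the 30 lists with a median (black bars), 1 list per line, ordered by median. Grey bars span the central 95% of the medians of 10000 random lists of equal size and signal; cholesterol synthesis genes lie highest at 0.93 and NF-kB and cytokine genes lowest at -0.86.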

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

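The tests on the NUP153 probe, on culture density, scaling and RNA quality were chosen only after the results were seen. The marker lists of placental, airway and intestinal cells were written before their values were looked up, but the count that includes the genes first left out of them was chosen afterwards.

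Probes without a gene symbol, which enter no count of genes, also held large differences. Of 3610 such measured probes, 163 were at least 2-fold higher on the array labelled NUP153 siRNA and 171 at least 2-fold lower, together 9.25%. Probe A_33_P3372212 had a log2 ratio of 4.01 and A_33_P3356935 of 3.36, and probes A_24_P68908 and A_24_P270460 were at -2.85 and -1.77. Probe A_24_P270460 is annotated to a coding RefSeq transcript for which the gene table gave no single symbol, so it may read a known gene.

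NUP153 RNA differed by a log2 ratio of -0.17 between arrays on which 1135 other genes differed by 2-fold or more. A decrease hidden by the normalization is argued against, since the lowest NUP153 ratio over all settings was -0.21. A probe too close to background is argued against as well: the control signal of NUP153 lay 6.44 log2 units above the lowest signal that counted as well above background. Arrays that carry each other's labels cannot be told apart from a correct labelling, because a ratio of -0.17 is too close to 0 to point either way. A knockdown that was incomplete or had recovered by day 3, a probe that reads a transcript spared by the siRNA, and a sample other than the labels state, stay open and untested.

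Differentiation genes were higher (median 0.65) while activation and NF-kB genes were lower (medians -0.80 and -0.86). Crowding of the cells, which favours differentiation, lowers YAP and TEAD targets. These stood higher, with a median of 0.61 at percentile 100 (0.078 with the distorted normexp correction). This argues against a denser culture acting alone. A denser culture together with another difference that raised these genes cannot be told apart with 1 array per group. The lowest differentiation median over the scalings was 0.61. This does not decide on a scaling upset by a few bright genes, because percentiles, medians and ranks hardly respond to a few genes. Spike-in scaling rests on other probes, but its 5 bright probes had raw log2 ratios from 0.21 to 0.68. The normexp correction, which is not a scaling, gave -0.17, and 0.42 once 5 aberrant spots were left out of its fit. Lower RNA quality or labelling yield stays open: the larger absolute median of the reference and ribosomal protein lists was 0.17, but scaling each array to its own 75th percentile holds abundant genes near 0. The siRNA treatment and any other difference between 2 single cultures, such as medium or passage, may each account for the pattern and were not tested.

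PSG genes, SCGB1A1 and OLFM4 (4.49, a glycoprotein of intestinal stem cells chosen after its value was seen) stood far higher on the array labelled NUP153 siRNA. Placental cells in the sample stay open, as the count includes the PSG genes that raised the question. With them, 31.6% of 19 detected syncytiotrophoblast genes were at least 4-fold higher. Of these 6, 5 were PSG genes and the other was CSH1 (2.28, but 0.59 without the filter on dim probes). Without the PSG family, 1 of 13 detected genes (7.69%) was at least 4-fold higher, and the median was 0.22. HSD17B1 stood at 1.26 and PAPPA at -1.85, while CGA, CYP19A1 and HSD3B1 were dim on both arrays. Airway secretory cells and intestinal cells in the sample stay open too, as their counts cannot decide either. At least 4-fold higher were 11.8% of 17 and 30.0% of 10 detected markers. All of these were genes first left out of the lists: SCGB1A1 and AGR2, and OLFM4, PHGR1 and AOC1. Without them, 0 of 15 airway and 0 of 7 intestinal markers were at least 4-fold higher. A further 4 airway genes and 1 intestinal gene had only a bound, which was 0 for BPIFA1 and BPIFB1. Counting all 5 as higher would bring the shares to 35.3% and 40.0%, or to 26.7% and 14.3% without the genes first left out. Cross-hybridization among PSG copies, which would raise the count of PSG genes, was not tested. An effect of the siRNA, and keratinocytes of another line or history in 1 of the samples, may each explain it and were not tested.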

How the results depend on the processing

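Spike-in scaling and the normexp fit without aberrant spots were chosen only after the results were seen. No paired analysis was possible because each group holds 1 array. NUP153 stayed within 2-fold under every setting, with a lowest ratio of -0.21. Median scaling, the authors' processed values and spike-in scaling kept the counts over all genes within 1.5 times and every list median and named gene within its spread. Counts within lists moved more: reference genes at least 2-fold lower went from 1 to 2 under all 3 settings, and under spike-in scaling ATF4 targets lower went from 3 to 5 and differentiation genes lower from 1 to 2. Of 148 named genes, 54 moved by more than 1.5-fold with the planned normexp correction, 34 with the refit without 5 aberrant spots and 6 without the filter on dim probes. Signal over background limits the dim genes: those that normexp reversed had control signals from -5.67 (FLG) to -1.43 (LCE1C).

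The planned normexp correction shifted the median of all genes to -0.35, with 300 genes at least 2-fold higher and 3880 lower. Its cause is shown: 5 spots on the control array had a local background far above their signal, and the fitted background mean was -431 with them and 4.54 without, against 4.88 on the other array. It reversed the medians of squamous regulators (-0.017), differentiation genes (-0.17) and p53 targets (-0.29), and the ratios of CDKN2B (-0.21), CXCL14 (-0.40), EPGN (-1.19), FLG (-1.88), KDM6A (-0.31), KRT23 (-0.99), LCE1C (-0.24), LORICRIN (-1.47), MUC16 (-0.86), SPC24 (-1.39), TGFB2 (-1.13), VWF (-0.35) and WTIP (-0.97). It moved the medians of basal (-0.11), AP-1 (-0.37), activation (-0.99), simple epithelial (-0.80), mesenchymal (-0.52), TGF-beta (-0.38), YAP and TEAD (0.078), NF-kB (-1.17), EGFR (-0.77), unfolded protein response (-0.027), ribosomal protein (0.53), reference (0.32), chromatin (0.038), melanocyte (-1.84), leukocyte (-1.20) and neuronal genes (-1.13). Without the 5 spots, normexp gave 379 higher and 333 lower genes, of which 373 and 331 were among the 612 and 523. Its medians were 0.42 for differentiation, -0.69 for NF-kB, 0.79 for cholesterol synthesis and 0.049 for melanocyte genes. Its offset of 50 pulls ratios of dim genes toward 0 by construction, and how many calls were lost to the offset was not tested.

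Without a filter on dim probes, 1270 genes were higher and 998 lower among 19708 genes. Of these, 584 and 502 were among the 612 and 523 called with the filter. The calls rose more steeply than the number of genes, which was 13976 with the filter. Whether noise of dim probes made the added calls was not tested. The medians were 0.44 for differentiation, -1.09 for activation, -0.30 for simple epithelial, -0.66 for NF-kB, -0.17 for ATF4, -0.69 for hypoxia and -0.27 for leukocyte genes. The filter at the median signal left 8473 genes, with 318 higher and 258 lower, and medians of -0.095 for basal, 0.82 for differentiation, -1.09 for activation, -0.39 for TGF-beta, 0.40 for p53, 0.031 for interferon and 1.097 for melanocyte genes. At 1.5-fold, 1743 genes were higher and 1517 lower, and at 3-fold 217 and 186, by construction. Quantile normalization gave a TGF-beta median of -0.39 and loess a ribosomal protein median of 0.10, and the cause was not tested. The brightest probe gave medians of 0.46 for differentiation and -0.11 for reference genes. LCE1C, whose probes disagree, reversed to -0.40 with the brightest probe and with the filter at the median signal. Random lists without matching put the chromatin list at percentile 97.49, just inside the central 95%.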

Other observations

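The gene families below were chosen after their values were seen, the test of neighbouring genes was written before its result was seen, and its values at larger distances were added afterwards.

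Several gene families of epithelial remodelling and detoxification were uneven, and some of their members stand in the lists described before. Of 15 measured matrix metalloproteinase genes, 5 were at least 2-fold lower on the array labelled NUP153 siRNA and 0 higher; beside MMP1 and MMP10 these were the macrophage elastase MMP12 (-2.82), the epithelial matrilysin MMP7 (-2.72) and the gelatinase MMP2 (-1.02, within 2-fold with the refitted normexp correction). Of 7 aldo-keto reductase genes, 5 were at least 2-fold lower and 0 higher, whereas both measured CYP3A genes, which encode drug-metabolizing cytochromes, were higher, CYP3A5 at 4.26 and CYP3A7 at 3.23. These are near-identical copies, so their values are uncertain as single genes. With the refitted normexp correction they were at 3.15 and 2.59, and CYP3A5 was at 3.09 without the filter on dim probes. Of 14 measured S100A genes, 4 were at least 2-fold lower, S100A8, S100A9, S100A12 (-2.56, but -1.77 with the refitted normexp correction) and the antimicrobial S100A7 (-1.53), and 0 were higher. Among 9 SERPINB genes, SERPINB2, an inhibitor of urokinase, stood at 2.92 (2.24 with the refitted normexp correction) while SERPINB3 and SERPINB4 stood at -5.48. Claudins, the tight junction proteins, had 1 of 14 at least 2-fold higher (CLDN8, 3.17, but 2.52 with the refitted normexp correction), 1 lower (CLDN2, -1.26, but -0.72 with the refitted normexp correction) and a median of 0.37. All 4 measured PSG genes were at least 4-fold higher, from 3.25 to 5.35, and 2 more were detected on that array only, while PSG11 was detected on the control array only and was at least 2.48-fold lower. The lowest of the 4, PSG8, was at 2.57 with the refitted normexp correction and at 4.64 with the brightest probe or the filter at the median signal.

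A hypothesis set before the test was that neighbouring genes differ together, which shared enhancers could produce. The log2 ratios of adjacent measured genes with unlike symbols had a Pearson r of 0.083 (Spearman rho 0.079) over 12952 pairs across genes, which are not independent replicates. Likeness was judged by 3 letters of the symbol, so related neighbours with unlike names could stay among the pairs. The highest r over 1000 permuted gene orders was 0.030. The r was 0.039 for genes 2 places apart, 0.014 for 5 places, 0.018 for 10 places and 0.0025 for 50 places. The relation is weak, and overlapping transcripts or regional base composition, which were not tested, might give it as well.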
